A study of Homo sapiens with 2 samples.

How the data were processed

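Chem-seq was performed by the authors on A549 cells, a human lung adenocarcinoma line, with 1 capture library and 1 input library. Per the labels' protocols, cells were treated with biotin-linked lurbinectedin at 300 nM for 4 h and fixed with 1% formaldehyde for 10 min, the sonicated chromatin was incubated with streptavidin beads, and libraries were amplified over 14 PCR cycles and sequenced as single reads of 50 bases. The labels give the input library the same protocol text and bead entry as the capture library, so how the input was set aside is not stated in the sources used here. CASAVA 1.8.2, Bowtie and MACS 1.4.2 and the genome build hg19 are named in the submitters' processing notes; the version of Bowtie is not given in the sources used here.

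The deposited table is a list of peaks called on the capture library against the input library. Per the file headers, MACS kept at most 1 tag per position, used an effective genome size of 2700000000 bp, a band width of 300 and a fragment length of 220 bp, scaled the larger library towards the smaller, took the local background over 1000 and 10000 bp, and kept peaks with a p-value under 1e-05. The authors called peaks once on single libraries, so a peak has no replicate. Tags are deposited as whole counts of distinct capture tags inside each peak. The fold enrichment is deposited as the ratio of the summit pileup to the local background, and the FDR is deposited as a percent. The score column was deposited with a spreadsheet error in place of its name; it was read as 10 times the negative log10 of the caller's p-value from its place and its lowest value, 50.01, which matches the threshold. Fold, score and FDR are the authors' own values for each peak and were used only to describe, rank and filter peaks within the list. Keeping 1 tag per position removed 25500238 capture tags, which limits the tags a peak could show. Peak numbers ran to 1186, of which 148 were absent from the rows used here; their tags, scores and positions were not used here, and only their place in the order of numbers entered the tests described as concerning absent numbers.

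Each peak's expected tags were obtained by solving the Poisson tail probability of its tags for the score. Division by the peak width (at least 440 bp, which is 2 fragment lengths) gave the local background, expressed in multiples of the genome mean, and the fold times this background gave the summit pileup. This rests on a model of how the caller computed its values and was checked on the list: 98.7% of the pileups were whole numbers within 0.05, and 96.5% of 737 backgrounds above the genome mean and below 3 times it were whole numbers of input tags per 10 kb within 0.1 of a tag, where chance gives 20%. On 1038 simulated peaks 100% of the pileups were recovered, which checks the arithmetic alone, because the simulation uses the same formula. Pileups of the 13 peaks outside the tolerance were rounded. The lower limit of 440 bp was set after the recovered pileups of short peaks had come out above their tags. All analyses of background, pileup and absent numbers, the limit of 3 times the genome mean and the minimum of 10 peaks per chromosome were chosen after the data were examined.

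Planned analyses of genomic location, promoter share, base composition, triplet content, gene lists and peak strength by location needed a genome or annotation of hg19, which was not used here; the reference gene table is on GRCh38.p14, and no coordinate was converted. No peak was therefore assigned to a gene, exon or intron, and the rule for named genes was applied to peaks: the 15 of highest fold and the 15 of highest score, ties by score and then by order. Peaks outside those 30 places are named as members of small sets chosen after their values were seen. The planned test of peaks per chromosome against the length of chromosomes was replaced, after the files had been seen, by a two-sided exact binomial test against each chromosome's share of 20037 protein-coding genes in the GRCh38.p14 table, with Benjamini-Hochberg adjustment. All chromosomes together were compared with gene share by a chi-square distance against 10000 random lists. Gene number is a stand-in that does not follow length. Per Mb between the first and last peak, chromosome 19 carried 25.0 genes and chromosome 18 carried 3.51. Membership of a chromosome was also taken from another build. On simulated lists of 1038 peaks with chromosome 7 doubled, the test called it in 99.5% of lists, and 5% of unchanged lists held a false call.

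Spacing was compared with 10000 sets of random positions between the first and last peak of each chromosome, leaving out its longest stretch without a listed peak in place of the planned assembly gaps. These stretches are not known to be free of called peaks, since 11 of the 23 hold 57 of the absent numbers. Correlations over all peaks and between chromosomes were tested with 100000 permutations. Correlations between peak measures under alternative settings used fewer permutations. The correlation of background between neighbouring peaks used 10000 shuffles. The correlation over windows within chromosomes used 2000 permutations. Tests across peaks treat positions as independent and describe this list only, not what another capture would give. Intervals of fold are exact Poisson intervals of the pileup at a fixed background, and do not allow for the selection of peaks by their own height. Alternatives fixed before the data were examined were peaks of at least the median score, an FDR of at most 1%, peaks of at least the median fold, chromosomes 1 to 22 and X, merging within 10000 bp, and neighbours within 100000 bp; those added afterwards left out peaks of high background, used the distance between first and last peak as denominator, kept the longest stretch among the random positions, or added the 140 absent peak numbers enclosed by a chromosome's peaks, and then also the 8 between chromosomes in the least favourable of 60 divisions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.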

Results

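The series asked where in the genome of A549 cells lurbinectedin is bound. A549 is a human lung adenocarcinoma line, and lurbinectedin is a synthetic alkaloid that binds guanines in the minor groove of DNA. Cells received a biotin-linked form of the drug at 300 nM for 4 h and were fixed with 1% formaldehyde. Streptavidin beads were used to pull down DNA fragments linked to the drug, which were then sequenced (Chem-seq). The data comprised 1 capture library and 1 input library, so no difference between them has a replicate check, and every test described here concerns positions within this single list of peaks. The capture library held 38139640 tags, of which 12639402 remained after duplicates were removed. The input library held 49348069 tags, of which 47414514 remained. The duplicate share was 66.9% in the capture library and 3.92% in the input library.

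Captured DNA was enriched over input at 1038 listed regions of the hg19 genome, spread over 24 chromosomes. No pull-down from cells without the biotin-linked drug is among the libraries. Binding of the drug at these regions therefore cannot be told apart from other capture by the beads. The regions were short, with a median width of 652 bp and a range from 418 to 5029 bp. Their enrichment was moderate and rested on few tags. The median fold enrichment at the summit, as the authors' peak caller gave it, was 7.78, with an interquartile range from 6.96 to 8.80 and extremes of 3.41 and 14.36. The median region held 14 capture tags (interquartile range 13 to 16), and 794 regions (76.5%) held between 12 and 16. The caller's false discovery rate did not exceed 0.26% for any region and was listed as 0 for 258 of them (24.9%). All regions together covered 721 kb, or 0.0267% of the effective genome size that the caller used, and held 16665 of the distinct capture tags. That was 0.132% of the library (95% Wilson interval 0.130% to 0.134%) and 3.72 times the 4477 tags that the caller's own local background implied for the same regions. Intervals cover counting error only.

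The local background behind each fold was recovered from the deposited values. It is the larger of the genome mean and the nearby input density scaled to the capture library, and it had a median of 1.10 times the genome mean. For 285 regions (27.5%) it lay at the genome mean within 0.001, the lowest value that the caller's rule allows. The summit of the median region carried 9 overlapping fragments where the genome mean was 1.03. Regions at the genome mean had a median fold of 8.74, and the other 753 regions had a median of 7.67. Across the 1038 regions, which are not independent replicates, fold fell as the local background rose (Pearson r = -0.35, Spearman rho = -0.48, each with a permutation p of 1e-05, the smallest that 100000 permutations can give). Fold contains the background as its divisor, and regions of higher background need less fold to pass the caller's threshold, so this relation is partly built into the list.

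**Figure D1:**
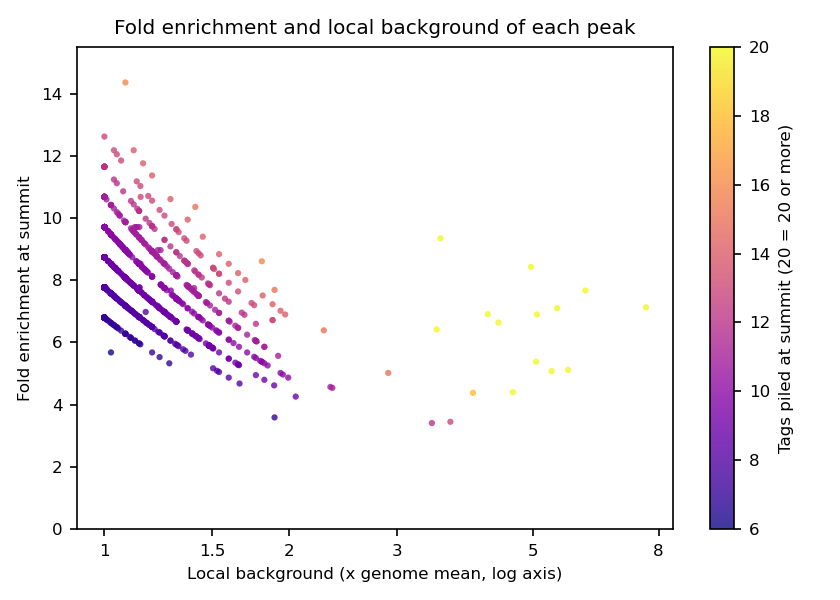
Fold enrichment at the summit (vertical axis) against local background in multiples of the genome mean (horizontal log axis) for each of the 1038 peaks, with colour giving the number of tags piled at the summit. Points at a background of 1 are the 285 peaks at the genome mean; the bands of points are whole numbers of tags, and the points to the right of 3 are the 16 peaks with the highest background.

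The strongest region by fold lay on chromosome 19 between positions 47551274 and 47551769 (496 bp), where 16 fragments overlapped at the summit and the fold was 14.36 (95% Poisson interval of the pileup 8.21 to 23.3). A region on chromosome X (118818652 to 118819230) followed at 12.62 (6.72 to 21.6). Regions on chromosome 11 (506630 to 507475) and chromosome 12 (110140088 to 110140506) each reached 12.18, and a region on chromosome 2 (120770576 to 120771352) reached 12.05. The 15 regions of highest fold all stood at 11.65 or above and each held 12 to 20 tags. Their local background was between 1.00 and 1.16 times the genome mean, and 9 of them lay at the genome mean. The Poisson intervals of these 15 regions overlap, so their order by fold is not resolved with so few tags.

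The regions of highest caller score held more tags at lower fold. A region on chromosome 16 (33293599 to 33294881) scored highest, at 192.83, with 91 tags and a fold of 8.43 (6.10 to 11.4). The widest region in the list, on chromosome 15 (20545199 to 20550227), held 236 tags at a fold of 5.12 (3.45 to 7.30) and scored 151.69. A pair of neighbouring regions on chromosome 20 (26189621 to 26190713 and 26188600 to 26189536) scored 132.79 and 125.1, and a region on chromosome 2 (87623517 to 87624468) scored 123.59. These 5 regions lay where the local background itself was 3.53 to 6.08 times the genome mean. What raised the input there was not tested, so their tags and scores need not reflect the drug alone. Only 1 region, the one on chromosome 19 at 47551274, was among both the 15 of highest fold and the 15 of highest score. In all, 16 regions had a local background above 3 times the genome mean, and they held 1132 tags, or 6.79% of the tags in the list. The highest background, 7.63 times the genome mean, was on chromosome 6 (119558387 to 119559237), where the fold was 7.13 (5.38 to 9.26). Others lay on chromosome 2 (133015830 to 133017322, and 133034260 to 133035296), chromosome 8 (82754122 to 82755135), chromosome 13 (28033540 to 28034240) and chromosome 17 (62915951 to 62918230).

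The listed regions were unevenly divided between chromosomes. Per Mb between the first and last region of a chromosome, chromosome 19 carried the most among chromosomes 1 to 22 and X, with 80 regions or 1.38 per Mb, followed by chromosome 17 with 68 regions or 0.854 per Mb. Chromosomes 16 and 15 carried 0.604 per Mb each. Chromosomes 13, 18, 20, 21, 22 and X, which each held fewer than 15 regions, together held 49 regions, 4.72% of the list. They carry 13.4% of protein-coding genes. The set was picked for holding few regions, so a low share follows from the choice. Chromosome Y held 2 regions, too few for a density.

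Relative to the number of protein-coding genes on each chromosome, 13 of 24 chromosomes departed from the expected number (two-sided exact binomial test, Benjamini-Hochberg adjusted over 24). More regions than expected lay on 5 chromosomes: chromosome 7 (80 regions, 1.65 times the expected 48.6, 95% exact interval 1.32 to 2.03, adjusted p = 0.000146), chromosome 10 (1.60 times, adjusted p = 0.00192), chromosome 15 (1.53 times, adjusted p = 0.0103), chromosome 5 (1.37 times, adjusted p = 0.0267) and chromosome 2 (1.34 times, adjusted p = 0.0164). Fewer lay on 8 chromosomes. Chromosome X held 9 regions where 43.9 were expected (0.205 times, 95% exact interval 0.0939 to 0.387, adjusted p = 5.10e-09). Chromosome 1 held 65 where 107 were expected (0.608 times, exact binomial test, adjusted p = 7.79e-05), and chromosomes 3, 11, 13, 20, 21 and 22 held between 0.242 and 0.706 times the expected number. Chromosome 19 did not differ from its gene share (1.06 times, 95% exact interval 0.850 to 1.31, adjusted p = 0.599), although it carried 3.74 times the number expected from the distance between its first and last region (adjusted p = 1.05e-21). With that distance in place of gene number, 7 of the 13 calls held, and chromosomes 2 and 5 lay at 0.990 and 0.978 times expectation. Calls were gained above expectation on chromosomes 19, 17 (2.31 times, exact binomial test, adjusted p = 3.38e-09) and 16 (1.64 times), and below it on chromosomes 4 (0.702 times), 8 (0.676 times) and 18 (0.318 times). With the 140 absent peak numbers that lie within a chromosome added, chromosome X stood at 0.321 times expectation and remained called, while the calls of chromosome 21 (0.569 times, exact binomial test, adjusted p = 0.219) and chromosome 15 (1.35 times, adjusted p = 0.0779) were lost and that of chromosome 16 (1.37 times, adjusted p = 0.0185) was gained. The call of chromosome 13 was also lost (0.55 times, exact binomial test, adjusted p = 0.0794) when the other 8 numbers, which lie between chromosomes, were divided in the way least favourable to the calls. The calls of chromosomes 1, 7 and X held under all 8 alternatives that were run, 1 of which, the FDR limit, left the list as it was. The call of chromosome 3 was lost without the 16 regions of high background (0.717 times, exact binomial test, adjusted p = 0.0564). Of the 13 calls, 5 held among regions of at least the median score and 5 among regions of at least the median fold, where chromosome 15 fell to 0.749 times expectation among regions of at least the median fold.

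**Figure D2:**
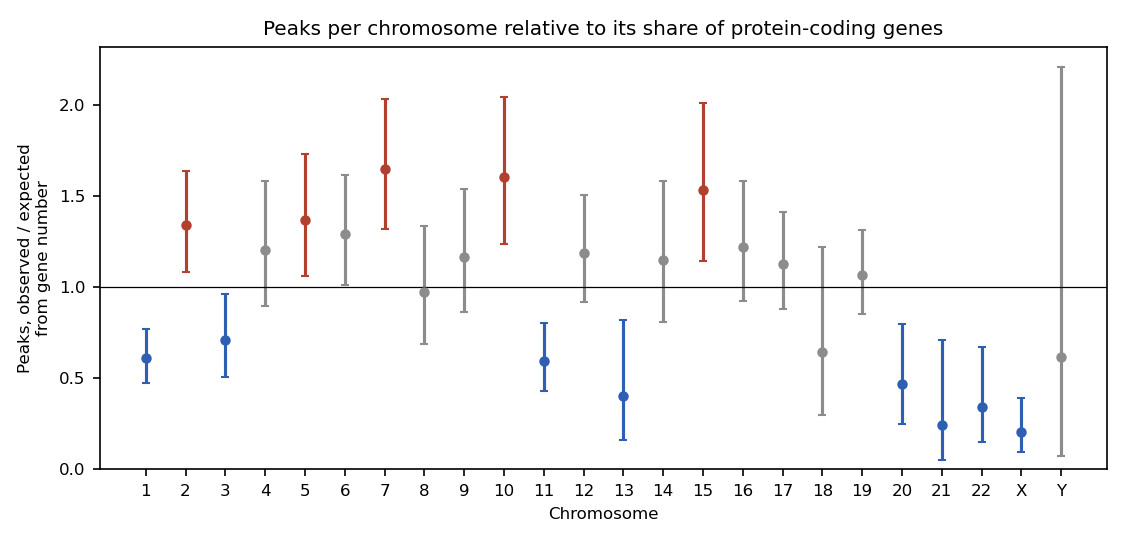
Number of peaks on each chromosome divided by the number expected from its share of protein-coding genes (points) with 95% exact binomial intervals (bars). Red points (chromosomes 2, 5, 7, 10 and 15) lie above expectation and blue points below it at an adjusted p under 0.05, and grey points did not pass; chromosome X is lowest at 0.205.

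The local background differed between chromosomes as well. Among chromosomes 1 to 22 and X it was highest on chromosome 15, with a median of 1.46 times the genome mean (interquartile range 1.31 to 1.54), and on chromosome 17, with a median of 1.4 (1.27 to 1.55). These chromosomes also had the lowest median folds of that set, 6.90 and 7.23. On chromosomes 13, 18, 20, 21, 22 and X, picked for holding fewer than 15 regions each, the median background was 1.00. Of their regions 75.5% lay at the genome mean, against 25.1% of the regions on all other chromosomes. The genome mean is the lowest value that the caller's rule allows, so an input density below it would not show. Chromosome X had the highest median fold, 9.71 over 9 regions. Among the 18 chromosomes with 10 or more regions, the number of regions per gene rose with the median background at Spearman rho = 0.52 (Pearson r = 0.45), but neither value passed after adjustment over the 3 relations computed between chromosomes (permutation tests, adjusted p = 0.0514 and 0.0814, raw p = 0.0296 and 0.0543). Without chromosomes 15 and 17, which lay farthest from the median background, r was 0.64 and rho was 0.54 (permutation p = 0.00734 and 0.0355). Over all 23 chromosomes but Y, rho was 0.75 (permutation p = 7.00e-05) and r was 0.58 (permutation p = 0.00152). That set adds the chromosomes with few regions, most of which lay at the lowest value the background can take. With regions per Mb in place of regions per gene, rho was 0.79 over the 18 chromosomes (permutation p = 0.000190). These last p-values are unadjusted. Regions per Mb rose with genes per Mb (Pearson r = 0.86, permutation adjusted p = 0.00348; Spearman rho = 0.51, adjusted p = 0.0514), but this rested on chromosomes 17 and 19, without which r was 0.17 (permutation p = 0.536). The relation of background with genes per Mb did not pass (r = 0.22, rho = 0.24, permutation p = 0.306 and 0.338).

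**Figure D3:**
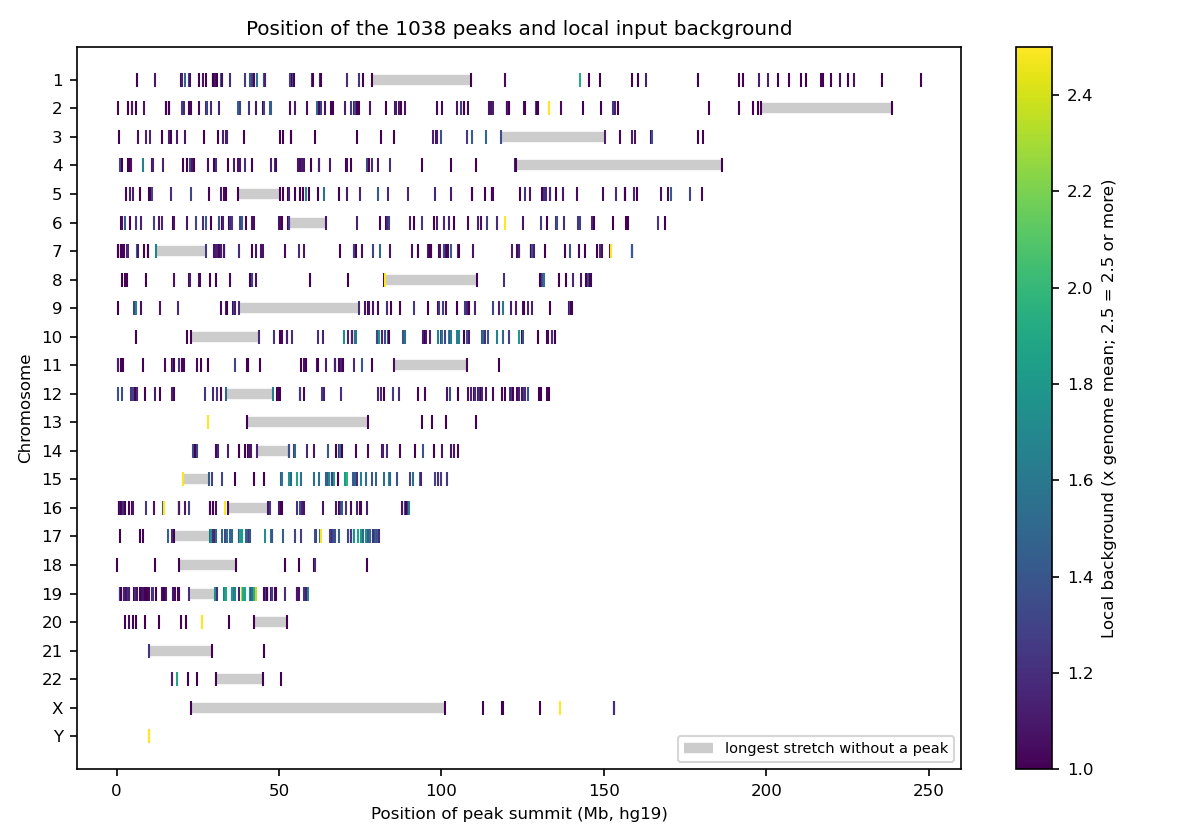
Summit position in Mb of hg19 (horizontal axis) of each of the 1038 peaks by chromosome (vertical axis); colour gives the local background in multiples of the genome mean and grey bars mark the longest stretch without a listed peak on each chromosome, and 11 of these 23 stretches hold absent peak numbers. Chromosomes 15 and 17 and part of chromosome 19 carry peaks of raised background, and chromosomes 13, 18, 21, 22, X and Y carry fewer than 10 peaks each.

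Within chromosomes, a small set of regions lay in close company. Of 1036 regions on chromosomes 1 to 22 and X, 27 (2.61%) had another summit within 10 kb, against a mean of 11.8 (1.14%) in 10000 sets of random positions (permutation test, two-sided p = 0.00560). The short arm of chromosome 19 gave several of these, with 3 regions between positions 913134 and 925937 and pairs starting at 1492110 and 3783869. Other pairs started on chromosome 16 at 19325554, on chromosome 5 at 109525576 and on chromosome 22 at 17043759. Some pairs almost touched. On chromosome 19 a region ended at 3784509 and the next began at 3784527. On chromosome 20 a region ended at 26189536 and the next began at 26189621. Such pairs may each be a single stretch that the caller divided, and they count among the 27. The test was not repeated without them. Within 100 kb, 137 regions (13.2%) had a neighbour against a random mean of 110 (10.6%, permutation p = 0.0486). Among regions of at least the median score or the median fold, the difference at 10 kb no longer passed (permutation p = 0.0612 and 0.115), with 1.95% against a random mean of 0.681% and 1.54% against 0.556%. These filters leave fewer regions, and the ratio to the random mean was not smaller. The densest windows of 5 Mb were the first of chromosome 19 with 13 regions and the next with 12, while the median window that held any region held 2.

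Across regions, width rose with the number of tags (Spearman rho = 0.80), and score rose with tags (0.47), with fold (0.26) and with width (0.20). Fold fell with tags (-0.27) and with width (-0.26). All 6 relations had a permutation p of 1e-05, the smallest that 100000 permutations can give, and remained past the threshold after adjustment over the 6. The caller computes score from tags and background, and fold from the summit pileup and background, so these relations are partly built in. Among regions of at least the median fold the relations of fold with width and tags were not past the threshold (rho = -0.03 for each), but that filter narrows the range of fold itself.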

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

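The tests of the duplicate share and of the runs of absent numbers were chosen after those values were seen; the test of the background beside the runs was fixed before its result. The duplicate tags entered no comparison, and the absent numbers entered alternative settings and the tests given here; the values stood above the input library or above the limit of 3 counts.

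Duplicates made up 66.9% of the capture tags and 3.92% of the input tags. Deeper sequencing of the capture library is argued against, because its total was 0.773 times that of the input. A capture library built from few distinct fragments stays open: a Poisson sampling model puts the share of distinct positions already seen at 94.2%, against 7.73% in the input. The model is computed from the duplicates themselves, so its outcome was fixed by the pattern and decides nothing. The listed peaks held 16665 distinct tags, 0.132% of the library, against 25500238 duplicates in all; duplicates within peaks were not analysed here.

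The peak numbers ran to 1186, and 148 of them (12.5%) were absent, in 38 runs of which the longest held 16. Random loss of single numbers is argued against, since 10000 random removals gave 122 to 137 runs in their central 95%. The long runs fell between listed peaks on chromosome 10 (22760817 to 43909600, 16 numbers), chromosome 11 (44056138 to 56915752, 14), chromosome 2 (88656528 to 98679417, 12) and chromosome 4 (48945298 to 55870045, 9). Of the 148, 57 lay inside the longest stretch without a listed peak on 11 chromosomes, so the absent numbers were not spread evenly. What marks these intervals was not examined, for want of an hg19 annotation. A candidate explanation is that regions of high input background were left out. Of the 70 peaks beside a run, 4.29% exceeded 3 times the genome mean, against 1.34% of the other 968. The difference did not pass (Fisher's exact test, p = 0.0873). The flanking peaks lay up to 78.2 Mb apart and are not the absent ones. The test therefore cannot show the background of the absent regions, and the explanation stays open. Why the numbers are absent is not given in the sources used here.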

How the results depend on the processing

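The alternatives on background, distance as denominator, absent numbers and the relation of background with peaks per gene were chosen after the data were examined. Of 127 alternative values with a test, 93 kept their direction and their side of the threshold, 31 kept the direction alone and 3 reversed. An FDR limit of 1% removed no peak, tests nothing and is left out of these counts. Restriction to chromosomes 1 to 22 and X removed only the 2 peaks of chromosome Y and changed no call. Its values remain among the 93 although they could hardly differ. Its spacing test was the main one again, because chromosome Y never entered that test. The list held 519 peaks at or above the median score and 520 at or above the median fold, by construction. The 13 chromosome calls became 5 under each of these filters, where fewer peaks were tested. Reversed values, none of them past the threshold, were on chromosomes 15, 2 and 5. Chromosome 15 stood at 0.749 times expectation among peaks of at least the median fold. Its own median fold was 6.90 against 7.78 for the list, so that filter removed most of its peaks. Chromosomes 2 and 5 stood at 0.990 and 0.978 with distance as denominator. Their 87 and 64 peaks were unchanged, and the expected numbers rose from 65.0 to 87.9 and from 46.8 to 65.4. Of the 31, 25 were chromosome values, among them chromosomes 15 and 21 when the 140 absent numbers within chromosomes were added, and also chromosome 13 when the 8 between chromosomes were divided least favourably (10 of 13 calls held). The share of peaks with a neighbour within 10 kb was 1.95% at or above the median score (random mean 0.681%) and 1.54% at or above the median fold (random mean 0.556%), against 2.61% and 1.14% for all peaks; neither passed, from fewer peaks, and the ratio to random did not fall. The relation of background and peaks per gene had rho = 0.19 among peaks of at least the median fold, a filter that itself favours low background, and 0.41 with absent numbers added (unadjusted permutation p = 0.441 and 0.0881, against 0.0296 for all peaks); the cause of the second was not tested. The other settings gave 0.54 to 0.79, all past the unadjusted threshold, among them 0.75 over all chromosomes but Y (permutation p = 7.00e-05). Not run, for want of an hg19 genome or annotation, were all alternatives for location, promoter share, base composition, triplets, gene lists and strength by location. The low number of tags per peak limits the list: with 12 to 16 tags in most peaks, the order of the 15 highest folds is not resolved.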

Other observations

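The tests of background against peak number between chromosomes, of the distance from gene share and of neighbouring peaks, and the limits of the chromosome 19 block, were chosen after the values that prompted them were seen; the tests of 10 Mb windows, of absent numbers added and of chromosome ends were written before their results. The input background, recovered at each peak, varied in blocks along some chromosomes. On chromosome 19 the 22 peaks between 30 and 45 Mb had a median background of 1.81 times the genome mean (interquartile range 1.61 to 1.93), against 1.08 (1.00 to 1.17) for the other 58 peaks of that chromosome. The block's peaks held a median of 27 tags at a median fold of 5.86, and the others held 14 tags at 7.82. On chromosome 10 the 7 peaks between 100 and 105 Mb, a window also picked after its value was seen, had a median of 1.59, against 1.20 (1.03 to 1.49) for all peaks of that chromosome.

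A hypothesis is that the uneven spread of peaks over chromosomes partly follows copy number in this aneuploid line. A region with more input and more capture tags would pass a fixed threshold at a lower fold. Copy number was not measured here, and such a measure would be needed to test the hypothesis. Base composition and a preference of the drug for particular chromosomes were not tested either. Neighbouring peaks correlated in background rank at 0.21 once peaks above 3 times the genome mean were left out. Shuffles within chromosomes averaged -0.02 (permutation p = 1e-04, the smallest that 10000 shuffles can give). This test was chosen after the values that prompted it were seen, and it includes the peaks of the chromosome 19 and 10 blocks. It therefore partly restates those blocks and lends the hypothesis on copy number no support. The absent peak numbers are argued against as the whole cause, since 11 of the 13 chromosome calls held once the 140 within chromosomes were added, and 10 or 11 over the 60 divisions of the other 8 between flanking chromosomes. Detection through background stays open, as rho was positive throughout but passed its permutation test only in some settings. It was 0.52 over 18 chromosomes (permutation test, adjusted p = 0.0514, made the criterion after the unadjusted 0.0296 was seen). Over all but Y it was 0.75 (unadjusted permutation p = 7.00e-05), and per Mb it was 0.79 (permutation p = 0.000190). With absent numbers added it was 0.41 (permutation p = 0.0881), and among peaks of at least the median fold it was 0.19 (permutation p = 0.441). Over 181 windows within 17 chromosomes the mean rho was 0.14 (permutation p = 0.0975). Windows were kept only with at least 2 peaks, and chromosomes only with at least 4 such windows, so this mean omits sparse windows. Gene number is argued against as the whole cause, since the chi-square distance of the 24 chromosomes from gene share was 164 where 10000 lists drawn by gene share gave at most 37.8 in their central 95% (permutation p = 1e-04, the smallest they can give), and it also lay above that range for the filtered peaks and with absent numbers added; a part in the spread is not excluded.

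Chromosome ends are gene-rich, and peaks might have gathered there. On the 18 chromosomes other than 13, 14, 15, 21, 22 and Y, 63 peaks lay in the first 5 Mb and 44 in the next 5 Mb, a difference that did not pass (two-sided exact binomial test, p = 0.0814). Of the 63, 13 lay on chromosome 19, 10 on chromosome 16 and 8 on chromosome 7. Only short-arm ends were examined, and long-arm ends were not tested.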
